A study of Mus musculus with 9 samples.

How the data were processed

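RNA-seq was read from whole brains of mouse embryos at embryonic day 14 in 9 libraries: 3 controls (saline), 3 exposed to poly(I:C) and 3 exposed to valproic acid. Per the labels, total RNA was extracted with a column kit, depleted of ribosomal RNA and made into libraries with random fragmentation and a NEBNext Ultra kit. The authors deposited 1 table of raw read counts per Ensembl gene, and its values were used as deposited. Whole numbers, genes at 0 and totals of 15400000 to 19883100 counts per library fit that unit. Per the submitters' processing notes HISAT2 was the aligner and GRCm39 (mm39) the build. The counter, its strand setting and the annotation release are not given in the sources used here, so antisense and overlapping genes cannot be told apart and reads of paralogs and pseudogenes may be shared. The labels give no dose, day of exposure, litter, sex or batch. Replicates carry the numbers 1 to 3 in each group.

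The table held 56748 genes, 32102 of them with at least 1 count and 4675 without a symbol in GENCODE release M21, which supplied symbols and chromosomes only. That release rests on an earlier build than the one in the submitters' notes, so no coordinates are given. No library was left out. Within groups, pairs of libraries differed by a chi-square per degree of freedom of 3.94 to 6.46, more than counting error alone gives, so none was a copy of another.

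Genes were kept by filterByExpr of edgeR 4.0.16 (min.count 10, min.total.count 15), which left 17171 tested genes. Counts were scaled by trimmed mean of M-values (TMM) factors, 0.977 to 1.02. All 9 libraries were fitted together with a mean per group by edgeR's quasi-likelihood method, and each pair of groups was compared with its two-sided F-test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison. CPM values (counts scaled by library size in edgeR) use the TMM factors, and fold changes are those of the fit. The log2 values behind the principal components and the correlations between libraries use a prior count of 2. Mean log2 CPM values over sets of genes add 1 CPM to each value, which shrinks differences of genes with low CPM. A gene at 0 in a group is given a lower bound against a floor of 3 counts per library, which covers counting error only. R was version 4.3.3.

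Before the data were examined 34 gene lists were fixed for Notch components and targets, neural cell types, regions, other cell types a brain sample may hold, immune, stress and metabolic responses, histone deacetylases and autism risk genes. The cytosolic ribosomal, mitochondrially encoded and histone lists were set by symbol pattern. Each list with at least 3 tested members was compared with all other genes by camera of limma 3.58.1 (two-sided, preset inter-gene correlation 0.01), adjusted over the 34 lists of a comparison. Camera with an estimated correlation and limma's fry, which tests whether the genes of a list move one way on balance, were run beside it. The members called are counted over all genes tested and adjusted over the list alone.

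The genes named were set by a rule written before the data were examined. Among called genes with a mean of at least 1 CPM, an established symbol and groups that did not overlap, the 10 with the largest rise and the 10 with the largest fall were named in each comparison. Of each list up to 4 called members with the smallest adjusted p were named, or up to 2 members as values where none was called. Notch1, Dll1, Hes1 and Hes5 were named throughout, and up to 10 genes for the overlap. Genes named outside the rule are marked as looked up after their values were seen. Usp18 was named by the list part of the rule and Hbb-bh1 by both parts.

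The overlap of the comparisons with control was set beside 50 simulations with no effect and beside the overlap of independent lists. In these simulations all 9 libraries, the controls among them, were drawn from the control means. Alternatives fixed in advance were DESeq2 size factors in edgeR, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), only the 6 libraries compared, the replicate number as a block, summed Y-linked expression as a covariate, library sizes without mitochondrial, globin and ribosomal RNA genes, and leaving out each library in turn. Xist as a covariate, the sex covariates for lists and overlap, and counts without unnamed genes, pseudogenes and genes on the sex chromosomes were added after the data were seen.

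The method was tested on simulated data with the means and spread of these libraries, 50 genes changed at each of 4 sizes. For valproic acid against control it called 32% of genes changed 1.25-fold, 68% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 7.64% of calls false. For poly(I:C) against control the shares were 38%, 84%, 86% and 100% with 7.78% false, and for valproic acid against poly(I:C) 52%, 56%, 76% and 96% with 10.8% false. With 3 libraries per group, changes near 1.25-fold were thus often missed. A list of 14 genes shifted 1.25-fold was called in each comparison and 0 unchanged lists were called. The simulated genes were drawn independently, so these simulations cannot show false list calls that come from correlation between genes. In the data the estimated correlation was 0.537 for erythroid markers in valproic acid against control.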

Results

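RNA from whole brains of mouse embryos at embryonic day 14, a stage of active cortical neurogenesis, was measured in 9 libraries, 3 in each of 3 groups. The control group had received saline. The poly(I:C) group had been exposed to a synthetic double-stranded RNA that mimics viral infection and activates innate immunity, and the valproic acid group to an anticonvulsant that inhibits histone deacetylases. Exposure to either agent before birth is used to model autism spectrum disorder in mice. The series as a whole concerns Notch signalling, a cell contact pathway that keeps neural progenitors undifferentiated, in such mice, so Notch genes were read in every comparison. Totals ranged from 15400000 to 19883100 counts per library. The group means (mean ± SD, n = 3) were 18071400 ± 1647870 for control, 17915100 ± 755918 for poly(I:C) and 16720500 ± 1159920 for valproic acid. The biological coefficient of variation over all libraries was 7.44%. The labels do not say whether the libraries of a group came from different embryos or litters, so p-values measure only the spread between these samples, part of which may be technical. Sex-linked transcripts, given below, differed within the control group and within the poly(I:C) group. The libraries of these groups were thus not all repeats of the same embryo.

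Along the leading principal component (24.3% of the variance) the valproic acid libraries lay between 23.5 and 27.5, apart from the controls at -20.2, -16.9 and -7.48 and the poly(I:C) libraries at -18.5, -14.1 and 1.33. The next component (16.8%) parted control from poly(I:C). Sex-linked transcripts followed the groups in part. Xist, the RNA made from the inactive X chromosome of females, was at 981 to 1055 CPM in the 3 valproic acid libraries and in poly(I:C) replicate 3, and at no more than 0.236 CPM in the others. The summed Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at 196 to 201 CPM in control replicates 1 and 2 and poly(I:C) replicates 1 and 2, and at 0 in the others, so control replicate 3 had neither signal.

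**Figure D1:**
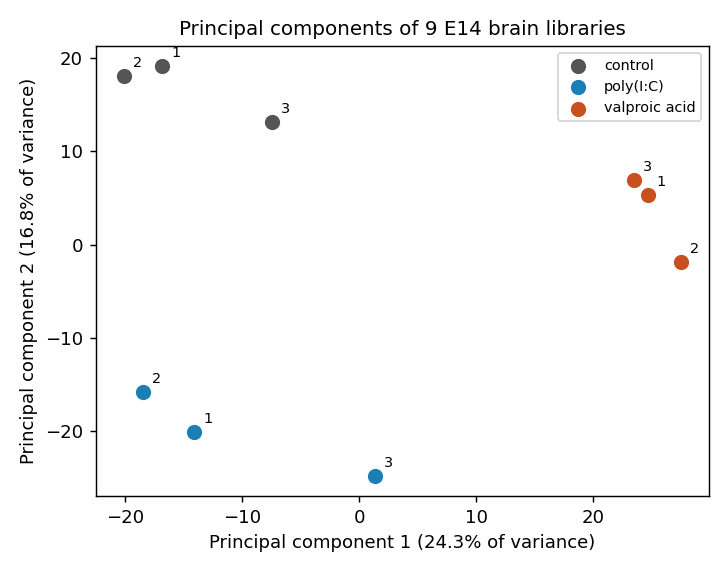
Principal components 1 (horizontal, 24.3% of variance) and 2 (vertical, 16.8%) of log2 CPM, unitless scores. Each point is a library, coloured by group and marked with its replicate number. The 3 valproic acid libraries lie at 23.5 or above on component 1, and poly(I:C) replicate 3, the highest of the other libraries, at 1.33.

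The comparison of valproic acid with control asked which transcripts differ in the brain of embryos exposed to valproic acid. Camera, which compares a gene list with all other genes, called the lists of cholesterol synthesis genes, proneural and intermediate progenitor markers, hypoxia and glycolysis genes and Notch pathway components higher under valproic acid with both a preset and an estimated correlation between genes. It called erythroid markers higher and postmitotic neuron markers and synapse genes lower with the preset correlation only (adjusted p = 0.14, 0.16 and 0.20 with the estimated one). Neurog2, a proneural transcription factor of the cortical excitatory lineage, rose from 145 ± 5.61 to 216 ± 6.90 CPM (mean ± SD, n = 3 per group; 1.49-fold, edgeR adjusted p = 7.7e-06). Mvd, an enzyme of the mevalonate pathway, rose from 36.0 ± 1.15 to 51.0 ± 2.61 CPM, and Ldha, the lactate dehydrogenase A subunit, from 243 ± 3.78 to 349 ± 17.9 CPM. Map2, a dendritic microtubule protein, fell from 1224 ± 40.2 to 1096 ± 35.8 CPM. Of 17171 genes tested, 1090 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 613 upward and 477 downward. Most changes were small: the median size was 1.20-fold, and 81 genes changed at least 2-fold. The count was 467 without control replicate 1, 709 without control replicate 2, 605 without control replicate 3 and 701 without valproic acid replicate 2. The call of Map2 was lost without control replicate 1 (edgeR adjusted p = 0.0845), control replicate 3 or valproic acid replicate 1. All 3 valproic acid libraries and no control held Xist, and the count was 277 with Y-linked expression as a covariate and 19 with Xist as a covariate, the latter fit chosen after the values were seen. For called genes off the X and Y chromosomes the median log2 size went from 0.267 to 0.263 with either covariate. Their median standard error rose from 0.0580 to 0.0714 and 0.106, and sex cannot be told apart from the exposure.

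In the cholesterol synthesis list 13 of 14 genes rose (13 adjusted over the list alone), with a median of 0.32 on the log2 scale (camera adjusted p = 6.4e-23, and 0.0045 with an estimated correlation). Besides Mvd these included Lss (lanosterol synthase, 1.28-fold) and Fdft1 (squalene synthase, 1.23-fold), with standard errors of 0.0395 to 0.0561 on the log2 scale and edgeR adjusted p of 2.5e-04 to 6.9e-04. In the hypoxia and glycolysis list 7 of 15 genes rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 1.6e-09, and 0.010 with an estimated correlation). The median of this list was 0.27 but its mean 0.06, and in mean log2 CPM over the list control replicate 3 lay above valproic acid replicates 2 and 3 (0.112 against 0.0928 and 0.0857, relative to the control mean). The glycolytic enzyme genes Ldha (1.43-fold), Pgk1 on chromosome X (1.39-fold), Eno1 (1.31-fold) and Aldoa (1.27-fold) were called at edgeR adjusted p of 1.7e-05 to 0.0012. Each of these named calls was kept in all 6 fits that left out 1 library. The gene that fell was Pfkp, a phosphofructokinase, looked up after the count was seen. Its call (edgeR adjusted p = 0.0247) was lost without control replicate 1 (0.0874), control replicate 2 or valproic acid replicate 2.

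Of 10 proneural and intermediate progenitor markers 7 rose (7 adjusted over the list alone; camera adjusted p = 1.9e-13, and 0.034 with an estimated correlation). Eomes, the transcription factor that marks intermediate progenitors, rose 1.29-fold, Hes6 1.22-fold and the antiproliferative gene Btg2 1.31-fold (edgeR adjusted p = 4.5e-04, 0.0022 and 0.0049). Of 14 radial glia and neural stem cell markers 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 9.0e-04, but adjusted p = 0.14 with an estimated correlation). Vim, an intermediate filament of radial glia, rose from 580 ± 15 to 703 ± 17.6 CPM, and the patterning regulators Pax6 and Gli3 rose 1.21-fold and 1.22-fold. Prom1 rose 1.20-fold and Tnc, an extracellular matrix gene looked up after its value was seen, fell by 0.31 on the log2 scale. Of 17 S phase genes 5 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.6e-04, but adjusted p = 0.17 with an estimated correlation), all of the minichromosome maintenance helicase: Mcm3 and Mcm5 rose 1.22-fold, Mcm7 1.17-fold, Mcm6 1.11-fold and Mcm2, looked up after the count was seen, by 0.18 on the log2 scale. Of 17 G2/M genes 3 rose (4 adjusted over the list alone; camera adjusted p = 6.7e-04, but adjusted p = 0.31 with an estimated correlation): the proliferation marker Mki67 (1.26-fold), cyclin B1 (Ccnb1, 1.17-fold) and Ube2c (1.19-fold).

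Of 16 postmitotic neuron markers 4 fell and none rose (9 fell adjusted over the list alone; median -0.12; camera adjusted p = 3.9e-04, but adjusted p = 0.16 with an estimated correlation): Map2, Stmn2, Mapt and Gap43, which encode cytoskeletal and growth cone proteins, were 1.12-fold to 1.13-fold lower. Of 23 synapse genes 5 fell (7 fell and 1 rose adjusted over the list alone; median -0.12; camera adjusted p = 0.0014, but adjusted p = 0.20 with an estimated correlation). Among them, the glutamate receptor subunit Gria2, the scaffold Shank2 and the adhesion molecule Nlgn3 (on chromosome X) were each 1.16-fold to 1.20-fold lower. Another was Nlgn1, looked up after the count was seen. Leaving out 1 library ended many of these smaller calls, with the highest edgeR adjusted p at 0.0945 for Prom1, 0.0594 for Mki67, 0.0526 for Mcm7, 0.128 for Mcm2, 0.123 for Tnc (lost without control replicates 2 or 3 or valproic acid replicates 1 or 2), 0.120 for Gap43, 0.0815 for Gria2 and 0.0811 for Stmn2. By contrast, Neurog2, Eomes, Hes6, Btg2, Vim, Pax6, Gli3, Mcm3 and Mcm5 stayed called in all 6 fits. With Y-linked expression as a covariate Neurog2, Eomes, Hes6, Vim and Pax6 of these stayed called, and with Xist only Neurog2. Over all 85 genes named and called for valproic acid against control, the covariates ended 49 and 81 calls (that of Xist itself among the 81). Without control replicate 1 the calls of Prom1, Mcm7, Mcm6, Mcm2, Mki67, Ccnb1, Ube2c, Stmn2, Mapt, Gap43, Gria2, Shank2, Nlgn3 and Nlgn1 were lost, and every other library ended at least 1 of them.

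Notch receptors and a ligand rose while the classical Notch targets gave no call. Of 27 Notch pathway components 5 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.10; camera adjusted p = 6.4e-05, and 0.032 with an estimated correlation). Notch1 rose from 142 ± 6.30 to 188 ± 16.6 CPM (log2 change 0.41, SE 0.0577, edgeR adjusted p = 0.0012) and Notch2 from 93.6 ± 2.21 to 124 ± 16.8 CPM (0.40, SE 0.0745, edgeR adjusted p = 0.0063). Mfng, a glycosyltransferase that modifies Notch receptors, rose 1.23-fold, and the ligand Dll1 rose from 68.2 ± 0.163 to 80.2 ± 3.95 CPM (edgeR adjusted p = 0.0155). Notch3 rose by 0.25 and Neurl1a, a ubiquitin ligase of Notch ligands, fell by 0.36 on the log2 scale; both were looked up after the count was seen. Of 8 Notch target genes 0 were called by edgeR (0 adjusted over the list alone), and the list median was 0.01 (camera adjusted p = 0.62). Hes1, a transcriptional repressor induced by Notch, was at 15.3 ± 1.5 CPM in control and 15.5 ± 0.507 CPM under valproic acid (log2 change 0.02, SE 0.0904, edgeR adjusted p = 0.94). Hes5, another such repressor, was at 14.1 ± 3.30 and 18.7 ± 2.63 CPM (0.41, SE 0.145, edgeR adjusted p = 0.11), and Hey1 at 29.3 ± 1.48 and 34.3 ± 0.830 CPM (edgeR adjusted p = 0.0989). Of the 8, 3 passed an unadjusted p of 0.05, not all in the same direction. Hey1 and Hes5 were higher and Dtx1 lower, at 139 ± 3.07 CPM in control and 131 ± 0.688 CPM under valproic acid. Limma's fry did not call the list either (adjusted p = 0.27). The call of Dll1 was lost without control replicate 1 or valproic acid replicate 2 (edgeR adjusted p = 0.0537). Those of Notch3 (highest adjusted p 0.122, lost in all but 1 fit, the one without valproic acid replicate 1) and Neurl1a (0.0982, kept only without control replicate 1 or valproic acid replicate 1) were weaker still.

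**Figure D2:**
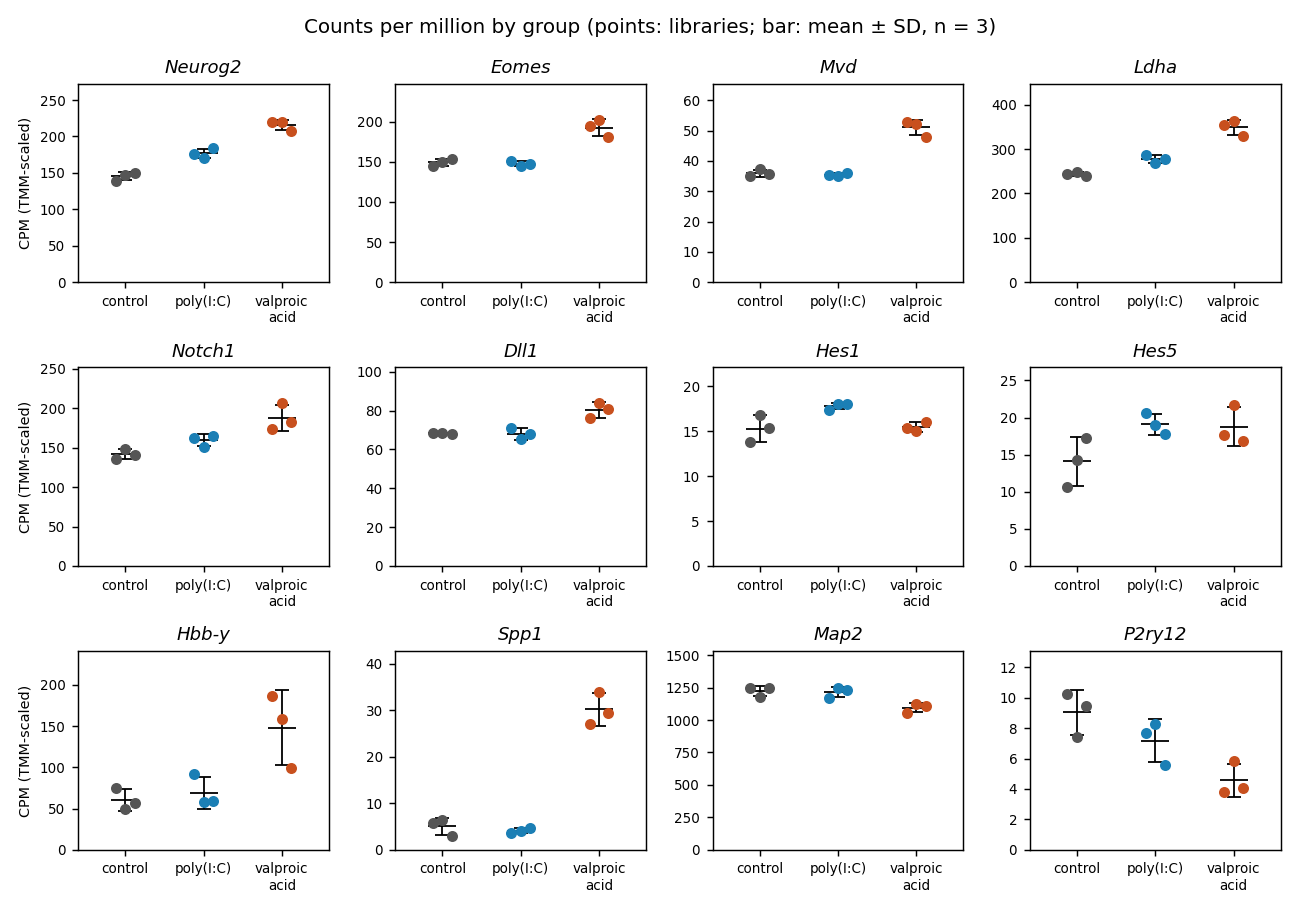
CPM (vertical, scaled by trimmed mean of M-values factors, axis from 0) of 12 genes in the control, poly(I:C) and valproic acid groups. Points are libraries, and bars give the mean ± SD (n = 3). Neurog2, Eomes, Mvd, Ldha, Notch1 and Spp1 are higher under valproic acid than in control, while Hes1 overlaps between those groups.

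Embryonic globin genes rose under valproic acid, an interferon-induced gene, Bst2, rose, and the microglial receptor gene P2ry12 fell. Of 10 erythroid markers 4 rose (6 adjusted over the list alone; median 0.77; camera adjusted p = 1.1e-09, but adjusted p = 0.14 with an estimated correlation). The embryonic globin Hbb-y rose from 60.2 ± 13.1 to 148 ± 45.1 CPM (edgeR adjusted p = 0.0031). The embryonic globins Hba-x and Hbb-bh1 rose 2.30-fold and 4.95-fold. Slc4a1, the anion exchanger of the red cell membrane, rose 2.80-fold. The adult globin Hbb-bs, looked up after its value was seen, was at 555 ± 34.3 and 602 ± 35.7 CPM (edgeR adjusted p = 0.52). Of 15 interferon response genes 2 rose (8 rose and 1 fell adjusted over the list alone; median 0.72; camera adjusted p = 2.4e-05, but adjusted p = 0.10 with an estimated correlation). Bst2, an antiviral membrane protein, rose from 3.55 ± 0.790 to 7.28 ± 0.513 CPM. Usp18, a negative regulator of interferon signalling, rose from 0.130 ± 0.0415 to 0.862 ± 0.215 CPM. Both levels lie under the minimum of 1 CPM set for the largest changes, so few reads stand behind them. Of 14 microglia markers 2 fell (2 adjusted over the list alone, median -0.15). Camera did not call the list (adjusted p = 0.052), while fry did (adjusted p = 0.033). P2ry12, a purinergic receptor of homeostatic microglia, fell from 9.04 ± 1.48 to 4.56 ± 1.11 CPM (edgeR adjusted p = 0.0094). Csf1r, the receptor that microglia need to survive, was 1.31-fold lower, a call lost without control replicate 3 (edgeR adjusted p = 0.0793) or valproic acid replicate 1. The lists of inflammatory cytokines and NF-kB targets (0 of 7 called by edgeR), choroid plexus markers (0 of 8) and skin, muscle and cartilage markers (0 of 3) were not called (camera adjusted p = 0.99, 0.67 and 0.21). EdgeR gave the same counts of 0 adjusted over the list alone. In the endothelial list Pecam1 rose 1.18-fold (1 of 10; 2 adjusted over the list alone; camera adjusted p = 0.77). In the mural cell and fibroblast list Rgs5 was 1.20-fold lower (1 of 10; 2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.31). The call of Pecam1 was lost without control replicate 3 (edgeR adjusted p = 0.108), control replicate 1, valproic acid replicate 2 or valproic acid replicate 3, and that of Rgs5 without control replicate 1 (0.0673).

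Of 93 genes in the cytosolic ribosomal protein list 35 rose and 2 fell (48 and 3 adjusted over the list alone; median 0.15; camera adjusted p = 4.4e-12, but adjusted p = 0.15 with an estimated correlation). Among those that rose, Rpl23 was 1.21-fold and Rpl13a 1.45-fold higher. The list was set by a symbol pattern that also takes kinases of ribosomal protein S6. The genes that fell, looked up after the count was seen, were such a kinase, Rps6kc1, and Rps3a3, a copy of Rps3a1 whose reads may be shared with other copies. Of 25 mitochondrially encoded genes 4 rose (5 adjusted over the list alone; camera adjusted p = 3.4e-05, but adjusted p = 0.28 with an estimated correlation). They were the ribosomal RNAs mt-Rnr2 (1.42-fold) and mt-Rnr1 (1.20-fold), mt-Co1 (1.09-fold) and the transfer RNA mt-Te (1.99-fold). In the unfolded protein and amino acid stress list Shmt2 and the chaperone Hspa5 rose (2 of 15; 6 adjusted over the list alone; camera adjusted p = 0.0021, but adjusted p = 0.084 with an estimated correlation). In the Hedgehog list Smo and Gli3 rose (2 of 9; 3 adjusted over the list alone; camera adjusted p = 0.0014, but adjusted p = 0.15 with an estimated correlation). In the forebrain list Lhx2 and Emx1 rose (2 of 6; 3 adjusted over the list alone; camera adjusted p = 0.017, but adjusted p = 0.15 with an estimated correlation). The calls of Rps6kc1 (highest edgeR adjusted p 0.0959), Rps3a3 (0.133), mt-Te (0.0853), mt-Rnr1 (0.117), mt-Co1 (0.130), Shmt2 (0.0652), Hspa5 (0.133), Lhx2 (0.0807) and Emx1 (0.107) were lost when a library was left out. Control replicate 1 ended the calls of mt-Te, mt-Rnr1, mt-Co1, Shmt2, Hspa5, Lhx2 and Emx1, and each of the other libraries ended at least 2 of these 9.

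The other lists were not called by camera, though fry called the Wnt pathway list (adjusted p = 0.0068). In the Wnt pathway list 3 of 19 genes rose (3 adjusted over the list alone; camera adjusted p = 0.14): Ctnnb1, which encodes beta-catenin, Tcf7l1 and Nkd1. Of 28 autism risk genes 4 fell and 1 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.62). Among those that fell, the sodium channel gene Scn2a was 1.19-fold lower and Nlgn3 1.20-fold lower. The histone methyltransferase gene Kmt2a rose 1.20-fold. In the immediate early list Jun and Ier2 rose (2 of 10; 2 adjusted over the list alone; camera adjusted p = 0.22). In the cortical layer list 1 of 12 genes fell (1 adjusted over the list alone; camera adjusted p = 0.67). The linker histone gene Hist1h1c rose from 8.47 ± 1.51 to 19.3 ± 1.83 CPM as the only call by edgeR among 21 replication-dependent histones (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.95). EdgeR called 0 of 12 histone deacetylases (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.95). It called 0 of 12 p53 targets, 10 folate and one-carbon genes, 14 GABAergic lineage genes, 5 oligodendrocyte precursor markers and 3 midbrain and hindbrain markers, and 0 in each adjusted over the list alone. Their camera adjusted p were 0.97, 0.62, 0.67, 0.66 and 0.62. Leaving out 1 library ended the calls of Ctnnb1, Tcf7l1, Nkd1, Ier2 and Scn2a (without control replicate 1, edgeR adjusted p = 0.154, 0.159, 0.165, 0.135 and 0.0845) and Kmt2a (without valproic acid replicate 2, 0.119).

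**Figure D3:**
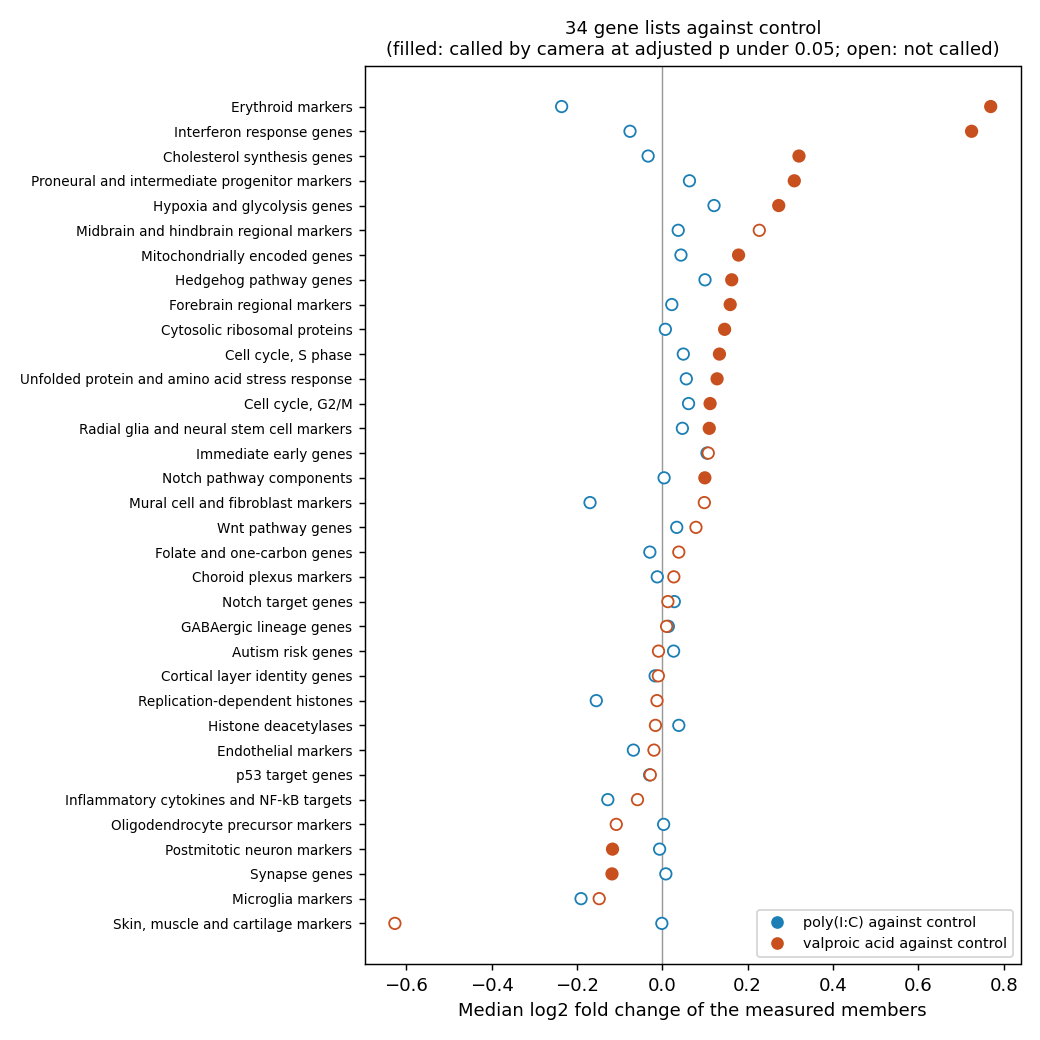
Median log2 fold change against control (horizontal) of the measured members of 34 gene lists (vertical) under poly(I:C) and valproic acid. Filled points were called by camera at an adjusted p under 0.05 and open points were not: 16 lists are filled for valproic acid and 0 for poly(I:C).

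Among genes with an established symbol, at least 1 CPM and groups that did not overlap, the largest rise apart from Xist was that of Spp1, which encodes the secreted glycoprotein osteopontin. It went from 5.03 ± 1.86 to 30.2 ± 3.50 CPM (6.07-fold, edgeR adjusted p = 7.7e-06). Hbb-bh1, Slc4a1 and Hbb-y were also among the 10 largest. The others were the small nucleolar RNA Snora57 (3.15-fold), Dnm3os (2.87-fold, antisense to Dnm3 and not told from it without strand), Exoc3l2 (2.57-fold), Cd14 (a co-receptor for bacterial lipopolysaccharide, 2.31-fold) and a gene ID that shares the symbol Myl12b with another and is uncertain. Among the same genes the largest falls were those of Samd11 (3.93-fold lower), Cdhr3 (3.69-fold), Ky (3.37-fold), Plac9a (2.92-fold), Ephx2 (soluble epoxide hydrolase, 2.79-fold), Ccdc36 (2.55-fold), Tmem254a (2.49-fold), Ociad2 (2.33-fold), Acta2 (smooth muscle actin, 2.22-fold) and Cd163 (a macrophage receptor for haemoglobin, 2.13-fold). Plac9a and Tmem254a belong to duplicated gene families and are uncertain. In all 6 fits with 1 library left out Spp1, Hbb-bh1, Slc4a1, Hbb-y, Samd11, Cdhr3, Ky, Ociad2 and Acta2 stayed called. The call of Cd14 was lost in every such fit (highest edgeR adjusted p 0.129), and those of Ccdc36 and Cd163 in 5 of 6 (0.111 and 0.114). Those of Xist (0.0569), Snora57 (0.0633), Dnm3os (0.0759), Exoc3l2 (0.139), Myl12b (0.231), Plac9a (0.0781), Ephx2 (0.0838) and Tmem254a (0.0687) were lost in at least 1, control replicate 1 among them for all but Dnm3os.

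The comparison of poly(I:C) with control asked what immune activation had changed in the brain by the same day. The changes were few. Tuba4a, an alpha-tubulin gene, rose from 3.15 ± 0.623 to 7.38 ± 1.36 CPM (2.35-fold, edgeR adjusted p = 0.0059). Mt3, a brain metallothionein that binds zinc and copper, rose from 42.4 ± 4.02 to 78.3 ± 0.594 CPM (1.85-fold, edgeR adjusted p = 0.0011). Neurog2 rose from 145 ± 5.61 to 177 ± 6.66 CPM (1.22-fold, edgeR adjusted p = 0.0061). Hmgb1, a chromatin protein that acts as an alarm signal outside cells, fell from 178 ± 22.6 to 98.6 ± 4.13 CPM (1.81-fold lower, edgeR adjusted p = 0.0021), but its read count may be shared with pseudogenes. Of 17171 genes 92 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 45 upward and 47 downward, with a median size of 1.43-fold. Of these, 26 changed at least 2-fold and 11 were annotated as pseudogenes. DESeq2 called 170. The count was 38 without control replicate 1, 60 without control replicate 2, 54 without control replicate 3, 39 without poly(I:C) replicate 1 and 46 without poly(I:C) replicate 3. It was 44 without unnamed genes, pseudogenes and genes on the sex chromosomes and 43 with Xist as a covariate, both chosen after the data were seen.

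Several of the large changes under poly(I:C) lay in multi-copy families and are uncertain where copies share reads. Rps3a2 fell from 233 ± 85.3 to 2.70 ± 0.328 CPM (86.1-fold lower) and Rps3a3 from 162 ± 50.9 to 1.81 ± 0.259 CPM (89.2-fold lower; edgeR adjusted p = 5.9e-09 and 1.8e-09). Rps3a1, the ribosomal protein gene they copy, rose from 212 ± 157 to 640 ± 3.72 CPM. The sum of these copies was 607 ± 21.5 CPM in control and 644 ± 3.40 CPM under poly(I:C). Tpm3, a tropomyosin gene, was 1.85-fold lower and Rps2 3.05-fold lower, each with other annotated copies. After Tuba4a and Mt3, the largest rises outside these families, among genes with an established symbol, at least 1 CPM and groups that did not overlap, were those of Psmc3ip, a meiotic recombination factor (1.81-fold), Tma16 (1.75-fold), Invs, a ciliary protein (1.71-fold), Decr2 (1.60-fold), Zfp213 (1.53-fold), Fam210b (1.40-fold) and Saraf (1.28-fold). The protease gene Prss22 was at 9.22 ± 4.98 CPM in control and 0 under poly(I:C), at least 54.9-fold lower against a floor of 3 counts per library. Under valproic acid it was at 7.38 ± 6.39 CPM, on in replicates 1 and 3 and off in replicate 2. The other large falls were those of Ube2l6, an enzyme that conjugates the interferon-induced modifier ISG15 (2.69-fold lower), Ctsk (cathepsin K, 2.42-fold), Kcnmb2 (1.99-fold) and Rdm1 (1.62-fold). Tuba4a, Mt3, Psmc3ip, Tma16, Fam210b, Rps3a2, Rps3a3, Tpm3, Hmgb1 and Neurog2 stayed called in all 6 fits with 1 library left out. The calls of Saraf, Prss22 and Rps2 were lost in every such fit (highest edgeR adjusted p 0.185, 0.160 and 0.160). Those of Rps3a1 (0.116), Decr2 (0.108), Zfp213 (0.196), Ube2l6 (0.0994), Ctsk (0.171), Kcnmb2 (0.146) and Rdm1 (0.160) were lost in 4 or 5 of 6, poly(I:C) replicate 1 or 3 among them, and that of Invs without control replicate 1 (0.0947) or control replicate 3.

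**Figure D4:**
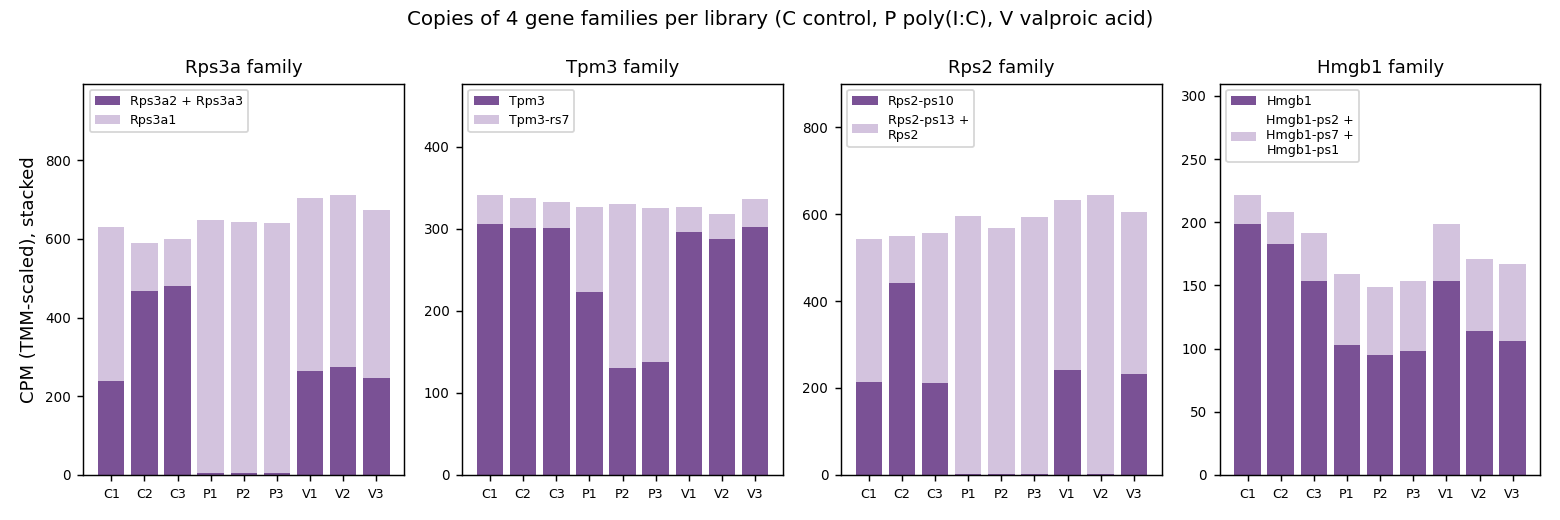
Stacked CPM (vertical, from 0) of the copies of 4 gene families in each library (horizontal; C control, P poly(I:C), V valproic acid). In the Rps3a family the sum is 607 ± 21.5 CPM in control and 644 ± 3.40 CPM under poly(I:C) (mean ± SD, n = 3), while Rps3a2 and Rps3a3 are near 0 in the 3 poly(I:C) libraries.

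No gene list was called for poly(I:C) against control. Camera called 0 of 34 lists with the preset correlation and 0 with an estimated correlation, fry called 0, and 11 lists had an unadjusted camera p under 0.05. The smallest adjusted p, 0.0593, was shared by mural cell and fibroblast markers (median -0.17), microglia markers (-0.19) and erythroid markers (-0.24) in the lower direction, and by proneural markers (0.06), G2/M genes (0.06) and hypoxia and glycolysis genes (0.12) in the higher direction. Interferon response genes, a readout of antiviral signalling, had a median of -0.08 (camera adjusted p = 0.65), with 0 of 15 called by edgeR (0 adjusted over the list alone). Ifit2 and Usp18, lowest in p, were at edgeR adjusted p of 0.24 and 0.42. Of the 7 measured inflammatory cytokines and NF-kB targets edgeR called 0 (0 adjusted over the list alone; camera adjusted p = 0.93), with Socs3 at 9.69 ± 1.40 and 11.4 ± 1.19 CPM (edgeR adjusted p = 0.58). None of 27 Notch components was called by edgeR (0 adjusted over the list alone): Notch1 was at 142 ± 6.30 and 160 ± 7.28 CPM (log2 change 0.17, SE 0.0578, edgeR adjusted p = 0.24) and Dll1 at 68.2 ± 0.163 and 68.0 ± 2.90 CPM (edgeR adjusted p = 0.98). Among the 8 Notch targets 0 were called (0 adjusted over the list alone), with Hes1 at 15.3 ± 1.5 and 17.8 ± 0.370 CPM and Hes5 at 14.1 ± 3.30 and 19.1 ± 1.42 CPM (edgeR adjusted p = 0.32 and 0.23). The number of lists called was 6 without poly(I:C) replicate 2, 5 without control replicate 3 and 1 without control replicate 1 or poly(I:C) replicate 1. It was 4 with Y-linked expression as a covariate, a fit chosen after the values were seen.

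The comparison of valproic acid with poly(I:C) tested the difference between the exposures directly, without the shared controls. Camera called the cholesterol synthesis list and the hypoxia and glycolysis list higher under valproic acid with both the preset and the estimated correlation. With the preset correlation only, it called the erythroid, interferon response, ribosomal protein and proneural lists higher and the neuronal and synapse lists lower (adjusted p from 0.053 to 0.15 with the estimated one). Spp1 was at 30.2 ± 3.50 against 4.08 ± 0.540 CPM (7.42-fold, edgeR adjusted p = 1.6e-06), Eomes at 193 ± 10.8 against 148 ± 2.96 CPM (1.31-fold, edgeR adjusted p = 4.4e-04) and Neurog2 at 216 ± 6.90 against 177 ± 6.66 CPM (1.22-fold, edgeR adjusted p = 0.0025). Of 17171 genes 445 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 243 higher and 202 lower under valproic acid, with a median of 1.24-fold. The count was 112 without poly(I:C) replicate 2, 181 without poly(I:C) replicate 3 and 266 without poly(I:C) replicate 1, 263, 294 and 259 without valproic acid replicates 1, 2 and 3, 111 with Y-linked expression as a covariate and 39 with Xist, a fit chosen after the values were seen. Of the 58 genes named and called, the covariates ended 33 and 46 calls. Camera called 12 of 34 lists, 10 higher and 2 lower, of which 2 were called with an estimated correlation.

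Of 14 cholesterol synthesis genes 12 were higher (13 adjusted over the list alone; median 0.36; camera adjusted p = 3.4e-30, and 0.0023 with an estimated correlation), among them Lss (1.33-fold), Mvd (1.44-fold), Hmgcs1 (1.29-fold) and Idi1 (1.52-fold), each called in all 6 fits with 1 library left out. Of 15 hypoxia and glycolysis genes 5 were higher (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 8.5e-06, and 0.040 with an estimated correlation): Pgk1, Ldha, Aldoa and Eno1, each 1.19-fold to 1.30-fold, and Pdk1, looked up after the count was seen, whose call was kept only without valproic acid replicate 3 (highest edgeR adjusted p 0.119). The median of this list was 0.20 but its mean -0.04. Of 10 erythroid markers 8 were higher (9 adjusted over the list alone; median 0.95; camera adjusted p = 3.5e-20, but adjusted p = 0.053 with an estimated correlation), with Slc4a1 2.83-fold and Hba-x 2.14-fold higher. Of 93 genes in the ribosomal protein list 23 were higher, the uncertain copies Rps3a2 and Rps3a3 among them, and 1 lower (49 and 2 adjusted over the list alone; camera adjusted p = 4.7e-23, but adjusted p = 0.059 with an estimated correlation). The lower gene, looked up after the count was seen, was Rps4l, lost without poly(I:C) replicate 2 (edgeR adjusted p = 0.142), valproic acid replicate 1 or valproic acid replicate 3. Of 10 proneural markers 4 were higher (8 adjusted over the list alone; camera adjusted p = 1.1e-08, but adjusted p = 0.059 with an estimated correlation): Eomes, Neurog2, Hes6 (1.22-fold) and Neurog1 (1.65-fold, lost in every fit with 1 library left out). Of 15 interferon response genes only Bst2 was called (2.24-fold; 8 adjusted over the list alone; median 0.85; camera adjusted p = 5.9e-08, but adjusted p = 0.053 with an estimated correlation). Of 10 mural cell and fibroblast markers 4 were higher (5 adjusted over the list alone; camera adjusted p = 9.7e-05, but adjusted p = 0.092 with an estimated correlation): the matrix genes Col1a1 (1.35-fold), Lum (1.36-fold), Col3a1 (1.27-fold) and Dcn (1.34-fold). The calls of Lum, Col3a1 and Dcn were kept only without valproic acid replicate 2. Of 25 mitochondrially encoded genes 1, mt-Rnr2 (1.23-fold), was higher (1 adjusted over the list alone; camera adjusted p = 0.0012, but adjusted p = 0.41 with an estimated correlation). Of 17 S phase genes 1, Mcm5, was higher (1.17-fold; 5 adjusted over the list alone; camera adjusted p = 0.041, but adjusted p = 0.41 with an estimated correlation). The calls of mt-Rnr2 (highest edgeR adjusted p 0.139) and Mcm5 (0.178) were kept only without valproic acid replicate 1 and valproic acid replicate 3 respectively. Camera no longer called the mitochondrial list without poly(I:C) replicate 3 or valproic acid replicate 2 (highest adjusted p 0.136) or the S phase list without poly(I:C) replicate 2, poly(I:C) replicate 3 or valproic acid replicate 2 (highest adjusted p 0.207).

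Of 16 postmitotic neuron markers 3 were lower under valproic acid than under poly(I:C) (9 adjusted over the list alone; camera adjusted p = 3.9e-05, but adjusted p = 0.13 with an estimated correlation): Gap43 (1.16-fold), Mapt (1.15-fold) and Map2 (1.11-fold). Of 23 synapse genes 2 were lower (8 adjusted over the list alone; camera adjusted p = 9.7e-05, but adjusted p = 0.15 with an estimated correlation): Nlgn3 (1.23-fold) and Shank2 (1.16-fold). Of 27 Notch components 3 were higher (4 adjusted over the list alone; camera adjusted p = 0.0028, but adjusted p = 0.059 with an estimated correlation). Notch2 was at 124 ± 16.8 against 88.7 ± 3.14 CPM (log2 difference 0.48, SE 0.0748, edgeR adjusted p = 0.0044), Dll1 at 80.2 ± 3.95 against 68.0 ± 2.90 CPM (0.24, edgeR adjusted p = 0.025), and Notch1 at 188 ± 16.6 against 160 ± 7.28 CPM (0.24, edgeR adjusted p = 0.043). Of 8 Notch targets edgeR called 0 (1 lower adjusted over the list alone; camera adjusted p = 0.77), with log2 differences of -0.21 for Hes1 (edgeR adjusted p = 0.26) and -0.03 for Hes5 (edgeR adjusted p = 0.95). Notch2 stayed called in all 6 fits with 1 library left out. The call of Notch1 was kept only without valproic acid replicate 1 (highest edgeR adjusted p 0.194) and that of Dll1 only without poly(I:C) replicate 1 or valproic acid replicate 1 (0.132). Those of Gap43 (0.0933), Mapt, Map2 (0.178), Nlgn3 and Shank2 were lost without poly(I:C) replicate 2 among others.

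Besides Spp1, Slc4a1 and Bst2, the large differences upward under valproic acid included those of Rps3a3 and Rps3a2 (58.1-fold and 57.6-fold, multi-copy and uncertain), the myeloid co-receptor Cd14 (2.96-fold), Hbb-bh1 (3.72-fold) and Ube2l6 (2.50-fold). Lower under valproic acid were Samd11 (4.0-fold), Cdhr3 (3.71-fold), Catsperg2 (2.89-fold), Plac9a (2.84-fold), Ccdc36 (2.82-fold), Pla2g7 (2.66-fold), Adamts7 (2.56-fold), Plekhn1 (2.03-fold) and Decr2 (1.97-fold). The transcription factor gene Sox12 was at 313, 316 and 160 CPM in the poly(I:C) libraries and at 0.175 to 0.234 CPM under valproic acid, but among the controls at 0.0590, 154 and 150 CPM. Left-out libraries ended the calls of Cd14 (highest edgeR adjusted p 0.0921), Hbb-bh1, Ube2l6 (0.0659), Samd11, Cdhr3, Catsperg2, Plac9a (0.152) and Ccdc36 (0.129), in most cases poly(I:C) replicate 2 or 3.

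The comparisons with control were set side by side to ask whether both exposures touched the same genes. Of the 92 genes called for poly(I:C), 43 (46.7%) were also called for valproic acid, all in the same direction, 26 higher and 17 lower. Lysosomal alpha-glucosidase (Gaa), Arl5a, the condensin subunit gene Ncapd2, Minar2 and the chloride transporter gene Slc12a2 fell in both, and Neurog2, Mt3, Psmc3ip, Tuba4a and Zswim5 rose in both. Levels of Gaa were 85.1 ± 6.34 CPM in control, 52.6 ± 6.69 CPM under poly(I:C) and 57.7 ± 2.53 CPM under valproic acid (edgeR adjusted p = 5.2e-04 and 0.0012). Those of Ncapd2 were 173 ± 7.49, 136 ± 5.71 and 137 ± 5.45 CPM. Independent lists of these sizes would share 1.61 genes upward and 1.31 downward. In 50 simulations with no effect, where both comparisons shared simulated controls, 0.1 genes were shared on average and 2 at most. With no effect an overlap near 0 is set by the design, so it cannot show how far lists of these sizes overlap through shared controls. Both comparisons use the same 3 controls, which are too few to split, so part of the excess may come from them. Across 15448 genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0336 against 0.0149 in the simulations, a difference of 0.0187. The correlation was 0.34 against 0.50 and the share with the same sign 68.7% against 66.5%. The overlap was 21 without control replicate 1, 23 without poly(I:C) replicate 1, 20 without poly(I:C) replicate 3, 26 without valproic acid replicate 3 and 75 by DESeq2. It was 206 with no filter on low counts and 26 with Y-linked expression as a covariate, the latter fit chosen after the values were seen. The call of Zswim5 under poly(I:C) was lost without control replicate 1, poly(I:C) replicate 1 or poly(I:C) replicate 3 (edgeR adjusted p = 0.0595).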

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

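The tests of the globins, of the Tpm3 family, of a fall of the called copies alone and of a strain or litter variant, and the fit with Xist as a covariate, were chosen after the results were seen. Of the 12 lists that camera called for valproic acid against poly(I:C), 7 also had opposite camera directions in the comparisons of the exposures with control. None of the 7 was called for poly(I:C) against control, so an opposite direction need not be an opposite response. The unadjusted camera p there was 0.85 for neuron markers, 0.69 for synapse, 0.68 for cholesterol and 0.47 for interferon genes. It was 0.035 for ribosomal, 0.010 for erythroid and 0.0018 for mural cell and fibroblast genes. Cholesterol synthesis genes differed by a median of 0.36 on the log2 scale (0.32 for valproic acid and -0.03 for poly(I:C) against control; camera adjusted p = 3.4e-30). Erythroid markers differed by 0.95 (0.77 and -0.24; camera adjusted p = 3.5e-20) and interferon response genes by 0.85 (0.72 and -0.08; camera adjusted p = 5.9e-08). Cytosolic ribosomal proteins differed by 0.14 (0.15 and 0.01; camera adjusted p = 4.7e-23) and mural cell and fibroblast markers by 0.23 (0.10 and -0.17; camera adjusted p = 9.7e-05). Postmitotic neuron markers differed by -0.12 (-0.12 and -0.01; camera adjusted p = 3.9e-05) and synapse genes by -0.12 (-0.12 and 0.01; camera adjusted p = 9.7e-05). The lower direction of the ribosomal list under poly(I:C) goes with a mean of -0.16 that rests mostly on Rps3a2 and Rps3a3 (-6.43 and -6.48), whose reads may be shared with other copies. With an estimated correlation only the cholesterol list of these 7 was called (camera adjusted p = 0.0023).

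The many genes called for valproic acid against control accompany a sex difference, since all 3 valproic acid libraries and no control held Xist. For the 1036 called genes off the X and Y chromosomes, the median ratio of the log2 change with the Y-linked covariate to that without it was 0.983 (quartiles 0.884 and 1.08; 0.978 with Xist). Of them 250 were still called with the Y-linked covariate and 12 with Xist, because the median standard error rose from 0.0580 to 0.0714 and 0.106 while the median size went from 0.267 to 0.263 in both. Although this ratio had been set beforehand to count against sex, sex cannot be told apart from the exposure, because poly(I:C) replicate 3 was the only library outside the valproic acid group with Xist, and control replicate 3, the other one without Y-linked expression, had no Xist (0.0498 CPM) and genes that escape X inactivation near the level of the libraries with Y-linked expression (6.34 against 6.22 to 6.32 in mean log2 CPM); these 2 libraries also lay nearest to the valproic acid group on component 1 (1.33 and -7.48). An earlier developmental stage, litter, which is not labelled, and the exposure itself as the biological explanation stay open too, and the stage cannot be told apart from the exposure: genes that decline with age minus genes that rise with age were 0.138 higher under valproic acid, but the libraries overlapped (-1.67 to -1.56 against -1.88 to -1.66). The poly(I:C) libraries lay at -1.53, -1.67 and -1.70 and overlapped both of these groups. High values were thus not particular to valproic acid.

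The erythroid markers that rose under valproic acid could come from more blood in those libraries or from blood of another make-up. Embryonic globins were higher by 1.17 and adult globins by 0.13 in mean log2 CPM, a difference of 1.04 against an SD of 0.166 among the controls, and higher in all 3 valproic acid libraries than in all 3 controls. This argues against more blood of the same make-up as the whole cause. A younger stage, in which primitive red cells still circulate, stays open because the stage lists did not decide, and a change in red cell maturation was not tested. The same difference was 0.52 for poly(I:C) against control. All 3 poly(I:C) libraries (-3.93, -3.99 and -3.35) also lay above all 3 controls (-4.45 to -4.12) in embryonic minus adult globins. The valproic acid libraries lay highest, at -3.26 to -3.19. A shift in this direction was thus not particular to valproic acid.

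Several large fold changes under poly(I:C) may reflect which copy of a gene family the reads were assigned to. In the Rps3a family the other copy gained 1.10 ± 0.32 (SE) of the CPM that the called copies lost, and in the Rps2 family the copies other than the called pseudogene Rps2-ps10 gained 1.12 ± 0.40, as reads moved between copies would give, while the fall of Rps2 itself from 7.52 to 2.46 CPM was not tested. The values argue against a fall of the called copies alone, since the other copies gained 428 ± 90.8 (SE) CPM in the Rps3a family, 130 ± 30.0 in the Tpm3 family (sum 336 ± 4.19 (SD) CPM in control and 327 ± 2.20 CPM under poly(I:C)), 322 ± 76.5 in the Rps2 family and 26.2 ± 4.64 in the Hmgb1 family. Opposite changes of the copies would offset the loss as well. In the Rps3a, Rps2 and Tpm3 families they cannot be told apart from moved reads. The Tpm3 family (share 0.932 ± 0.29) had also been seen before the test. For Hmgb1 (0.329 ± 0.080) moved reads and a change of the gene cannot be told apart. Its share lies between the bounds set, and copies under other names were not summed. A strain or litter variant could move reads in this way. For the changes under poly(I:C) it cannot be told apart from the exposure, because no label gives litter or strain. Of 21 genes on in some libraries and off in others, 3 followed the groups (Rps3a2, Rps3a3 and 1500004A13Rik), and 10 of 280 regroupings gave as many. The other 18, Xist, Prss22 and Y-linked genes among them, split the libraries of a group. An exposure shared by the group does not account for such a split. Rps3a2 and Rps3a3 together were at 238, 466 and 480 CPM in control replicates 1, 2 and 3. Rps2-ps10 was at 2.74 CPM in valproic acid replicate 2 but at 241 and 233 CPM in valproic acid replicates 1 and 3.

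Other splits of the 6 libraries of a comparison into 3 and 3 were fitted alone, and 10 splits are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, reached the real count. Every other split mixes the groups, so the difference between the groups adds to its spread. Low counts in those splits therefore follow whatever the cause of the difference. For valproic acid against control the real split called 836 genes and the highest other 3, for poly(I:C) against control 104 and 8, and for valproic acid against poly(I:C) 348 and 2.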

How the results depend on the processing

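DESeq2 size factors, library sizes without mitochondrial, globin and rRNA genes and a minimum of 1 CPM in 3 libraries kept the 3 gene counts within 1.5 times. The first of these moved the median log2 fold change by at most 0.0011. The Xist covariate, the Y-linked covariate for lists and overlap, and the count without unnamed genes, pseudogenes and genes on the sex chromosomes were chosen after seeing the data. For genes changed, valproic acid against control, the count was 1090 as reported, 1661 with no filter on low counts, 1247 by DESeq2, 277 with the Y-linked covariate, 19 with the Xist covariate, and 467 (without control replicate 1) to 789 (without valproic acid replicate 1) with 1 library left out. For genes changed, poly(I:C) against control, it was 92 as reported, 464 with no filter, 170 by DESeq2, 86 with the Y-linked covariate, 43 with the Xist covariate, 44 without unnamed genes, pseudogenes and sex-chromosome genes, and 38 (without control replicate 1) to 63 (without poly(I:C) replicate 2). For genes changed, valproic acid against poly(I:C), it was 445 as reported, 1057 with no filter, 111 with the Y-linked covariate, 39 with the Xist covariate, and 112 (without poly(I:C) replicate 2) to 294 (without valproic acid replicate 2). The unfiltered fits tested 32102 genes in place of 17171. For gene lists called, valproic acid against control, 16 were called as reported, 4 with an estimated correlation and 16 by fry. There were 15 with the Y-linked covariate, 14 with the Xist covariate and 16 to 18 with 1 library left out. Fry shared 14 of its 16 lists with those reported. It left out the mitochondrial and G2/M lists (fry adjusted p = 0.060 and 0.068) and called the Wnt pathway and microglia lists instead. For gene lists called, poly(I:C) against control, 0 were called as reported, 4 with the Y-linked covariate and 0 to 6 with 1 library left out (without control replicate 2 and without poly(I:C) replicate 2). For gene lists called, valproic acid against poly(I:C), 12 were called as reported, 2 with an estimated correlation and 14 by fry. There were 12 with the Y-linked covariate, 12 with the Xist covariate and 10 to 13 with 1 library left out. Of the 14 by fry, 10 were among those reported, without the mitochondrial and S phase lists (fry adjusted p = 0.15 and 0.11). The others were the endothelial, forebrain, unfolded protein and Wnt lists. For overlap of calls, valproic acid and poly(I:C) against control, 43 genes were shared as reported, 206 with no filter, 75 by DESeq2, 26 with the Y-linked covariate, and 20 (without poly(I:C) replicate 3) to 46 (without valproic acid replicate 1). With the replicate block the gene counts were 912, 88 and 340, the lists called 16, 2 and 11 and the overlap 42. The numbers do not pair the libraries: same-number pairs correlated at -0.04 to 0.13, and 3 of 9 libraries correlated best with their own number. Uncalled genes near 0 changed sign. Hes1, valproic acid against control, went from 0.02 to -0.0088 with the Xist covariate, -0.0512 without control replicate 1 and -0.0086 without valproic acid replicate 3 (0.0875 without control replicate 2). Dll1, poly(I:C) against control, went from -0.0052 to 0.0252 without poly(I:C) replicate 2 (-0.0366 without poly(I:C) replicate 1). Hes5, valproic acid against poly(I:C), went from -0.03 to 0.0839 with the Xist covariate, 0.0308 without poly(I:C) replicate 1, 0.0159 without valproic acid replicate 1 and 0.0451 without valproic acid replicate 3 (-0.147 without valproic acid replicate 2). Of the called named genes 42 of 85, 10 of 21 and 27 of 58 stayed called in all 6 fits with 1 library left out. Under the sex covariates standard errors were read only for genes called for valproic acid against control off the X and Y chromosomes, where they rose. The fits without the filter tested more genes. Apart from these points, the causes of the differences between settings were not tested.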

Other observations

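The stage lists read for the weighing of developmental age hold genes with roles in neural progenitors that the lists fixed in advance did not cover, and the early list's Igf2bp1 had been seen before the test. Of 7 genes that decline with age in neural progenitors, 3 rose under valproic acid against control: the RNA-binding protein genes Igf2bp1 (log2 change 0.28, SE 0.0513, edgeR adjusted p = 0.0063) and Igf2bp2 (0.32, SE 0.0733, edgeR adjusted p = 0.021) and cyclin D1 (Ccnd1, 0.27, SE 0.0612, edgeR adjusted p = 0.019). Camera gave the list an unadjusted p of 9.0e-04, but p = 0.076 with an estimated correlation. Igf2bp1 was called for poly(I:C) against control too (0.25, edgeR adjusted p = 0.043). The median of this list was 0.15 for valproic acid and 0.09 for poly(I:C) against control. Of 11 genes that rise with age, the glycolytic gene Aldoc rose (0.21, edgeR adjusted p = 0.029), and the nuclear factor Nfix and the lipid carrier Apoe fell by 0.24 and 0.21 (edgeR adjusted p = 0.010 and 0.027), with a camera p of 0.86. Lin28b was at -0.21 (edgeR adjusted p = 0.27) and Nfia at 0.12 (edgeR adjusted p = 0.15).

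Control replicate 3 held neither Xist (0.0498 CPM) nor the Y-linked genes (0 CPM). Its mean log2 CPM over 6 genes that escape X inactivation was 6.34, against 6.22 to 6.32 in the 4 libraries with Y-linked expression and 6.73 to 6.82 in the 4 with Xist. Sox12 was at 0.0590 CPM in control replicate 1, 150 to 316 CPM in the other control and the poly(I:C) libraries, and 0.175 to 0.234 CPM in the valproic acid libraries.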
